A study of Mus musculus with 6 samples.

How the data were processed

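The values are deposited counts of unique molecular identifiers (UMIs) per gene and cell, with no normalization. Per the labels' protocols, libraries were made with the 10x Genomics Chromium Single Cell 3' v2 chemistry, which tags the 3' end of each transcript. Per the submitters' processing notes, reads were processed with Cell Ranger 2.1 on mm10. The filters on cells and genes are not given in the sources used here. In the deposited table no immunoglobulin chain gene is present, every gene has a UMI in at least 81 cells (1.01%), and every cell has at least 299 genes and between 0.512% and 20.0% mitochondrial counts. The naive and 2 hr libraries hold 2000 cells each. Of the gene symbols 9703 (99.1%) matched the GENCODE M21 annotation of GRCm38 once.

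No cells, and so no doublets, were removed in the main analysis. Cells were assigned to groups from the library name given with each cell. With 1 library per group there were no replicates, so no test of a difference between groups was run. For each library the UMIs of all cells were summed and divided by the library's total and scaled to CPM, with exact 95% Poisson intervals. Ratios of CPM have exact conditional binomial intervals and shares of cells have exact Clopper-Pearson intervals, all for counting error only. A count of 0 was set to a floor of 3 counts and the ratio called "at least". Where the floor put the library with 0 UMIs above the other, the log2 ratio was set to 0. A gene was measured in a comparison with at least 20 UMIs and at least 10 CPM in 1 of its libraries. It was called higher or lower at a CPM ratio of 2 or above, or 0.5 or below.

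There were 7 comparisons, fixed before the data were examined. These were 2 hr with naive, the 3-day group with 2 hr and with naive, spleen short-lived with naive and with the 3-day group, bone marrow short-lived with spleen short-lived, and bone marrow long-lived with bone marrow short-lived. Gene lists were also fixed then. The biology lists were B cell identity, MHC class II, plasma cell program, unfolded protein response and ER secretion, immediate early and NF-kB response, MYC and ribosome biogenesis, DNA replication, mitosis, oxidative phosphorylation, glycolysis, amino acid transport and tRNA charging, survival and long-lived plasma cell genes, adhesion, homing and egress, chromatin architecture, interferon response, autophagy and proteasome, and the gate genes. Cell-type lists covered other blood, stromal and progenitor cells and B cell subsets. Each list median was placed among the medians of 10000 random lists of measured genes matched on mean expression in 20 bins and drawn with replacement, with seed 1. Of 118 biology list medians 79 lay outside the central 95%. Random members were drawn independently, while members of a list can vary together, and no spread between libraries enters. The percentiles are therefore descriptions of these libraries and not error rates. A list with fewer than 5 measured members has no median. Survival genes below stands for the whole list of survival and long-lived plasma cell genes. It also holds genes such as Bcl2l11 and Ccnd2, so its median does not by itself mean more or less survival.

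The genes named in the report follow a rule fixed in advance. It takes the 10 highest and 10 lowest ratios among measured genes with at least 50 CPM and a UMI in at least 10% of cells of the higher library, without immunoglobulin, ribosomal protein, mitochondrial and predicted genes and pseudogenes. It adds up to 4 members of each biology list with the largest ratios and 9 gate and transcription factor genes. The text prints part of these. For shares of cells, each cell was thinned at random to 800 UMIs and cells with fewer were left out.

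The method was tested on simulated data in which unchanged genes and genes set to a known fold were drawn at the depth of each library. Genes set to 4-fold were recovered in 100% of cases in each comparison. Genes set to 3-fold were recovered in 100% in 5 comparisons, in 95 of 98 (96.9%) for the bone marrow and spleen short-lived libraries, and in 91 of 93 (97.8%) for the bone marrow libraries. Of unchanged genes, between 0 and 66 were called, at most 1.07%. The intervals covered 93.2% to 95.7% of the genes. Counts were drawn as Poisson around 1 pooled proportion per gene, so the simulation held counting error and no spread between libraries or animals. Its rates are therefore not error rates of the calls between these libraries.

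Other settings, chosen before the data were examined, were TMM and median-of-ratios scaling, no gene minimum, at least 100 UMIs, cells with at least 500 genes and at most 10% mitochondrial counts, no cells over 3 times the median UMI count (a stand-in for doublet removal), no cells with at least 2 UMIs of another lineage's markers, the mean of per-cell CPM, equal depth, and thinning to 500 UMIs or none. A filter on 2 different markers of another lineage without Cst3, and median-of-ratios scaling over 4 libraries, were chosen after the data were seen. Chromatin contact and other data of the study were not analysed here. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and TMM in R 4.3.3 with edgeR 4.0.16.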

Results

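Mouse B lineage cells of 6 groups were profiled by droplet single-cell RNA sequencing, in which a unique molecular identifier (UMI) marks each captured transcript at its 3' end. There was 1 library per group and 6 libraries in all, from Blimp-GFP mice on the C57BL/6 background, in which green fluorescent protein reports Prdm1 (Blimp-1), the transcription factor that drives plasma cell differentiation. The groups were naive B cells of the spleen, CD23+ splenic B cells cultured with 10 µg/mL lipopolysaccharide (LPS) for 2 hr or for 3 days, short-lived plasma cells of the spleen, and short-lived and long-lived plasma cells of the bone marrow. Per the labels, the naive and 2 hr groups were CD23+ IgD+ CD19+, the 3-day group was also Blimp1+, and the plasma cells taken from mice were CD138+ Blimp+ and negative for IgD and for markers of other lineages. B220 separated short-lived (B220+) from long-lived (B220-) cells.

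The naive library had 2000 cells and 4877558 UMIs, the 2 hr library 2000 cells and 5904246, and the library labelled 3-day 1479 cells and 7511206. The library labelled spleen short-lived had 1372 cells and 7387257 UMIs. The bone marrow short-lived library had 154 cells and 1359210 UMIs, and the library labelled bone marrow long-lived 1029 cells and 14164896. Median UMIs per cell in that order were 1981, 2435, 4248, 4476, 8036 and 12903. Ribosomal protein genes took 35.4% of the UMIs in naive cells, 31.7% at 2 hr, 20.9% in the library labelled 3-day, 22.8% in the library labelled spleen, 23.6% in the bone marrow short-lived library and 38.8% in the library labelled bone marrow long-lived. With 1 library per group no difference below has a replicate check, and no test of a difference between groups was made. Values are summed UMIs per gene scaled to CPM, the usual unit of a library's counts, and the 95% intervals in parentheses cover counting error only.

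The genes behind the sorting gates were read in each library, since they check the labels. Prdm1 (chromosome 10, 44437177 to 44528501 in GRCm38, protein-coding) was at 1.85 CPM in naive cells and 1.69 CPM at 2 hr, against 53.0 CPM in the library labelled 3-day, 59.7 CPM in spleen, 67.7 CPM in bone marrow short-lived and 80.8 CPM in the library labelled bone marrow long-lived. Sdc1 (chromosome 12, 8771323 to 8793715, protein-coding), which encodes CD138, was at 442 CPM in the library labelled 3-day, 412 CPM in spleen and 580.5 CPM in bone marrow short-lived cells, but at 7.41 CPM in the library labelled bone marrow long-lived, close to the 8.41 CPM of naive cells. That level goes against the CD138+ label of the long-lived group. Fcer2a, which encodes CD23, was at 295 CPM in naive cells and 351 CPM at 2 hr, and at 1.33 CPM in the library labelled 3-day. CD23 was selected before culture, so this low level does not go against that label. A rotation of the 3-day, spleen and long-lived labels was left open by the closing tests, so these 3 libraries are called by their labels, and spleen below stands for the library of that label. Cd19 was at 298, 183 and 40.2 CPM in the naive, 2 hr and 3-day-labelled libraries, and at 7.17, 35.3 and 102 CPM in the spleen, bone marrow short-lived and long-lived-labelled libraries. Ptprc was at 81.7 CPM in bone marrow short-lived cells and 95.1 CPM in the library labelled bone marrow long-lived, but a 3' tag does not see the B220 isoform, so Ptprc checks nothing about B220. Xist, expressed from the inactive X chromosome of female cells, was at 767 to 1178 CPM in 5 libraries and at 3.11 CPM in the library labelled bone marrow long-lived, where the Y-linked Ddx3y was at 28.2 CPM and Eif2s3y at 60.5 CPM.

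**Figure D1:**
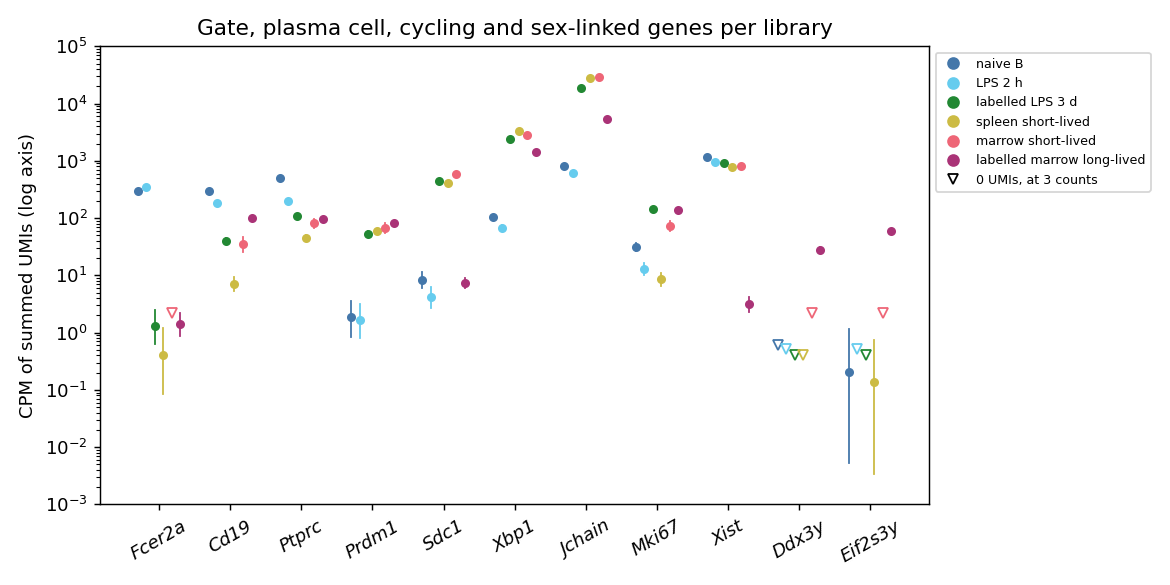
CPM of summed UMIs on a log axis for gate, plasma cell, cycling and sex-linked genes, with 1 point per library and bars for 95% Poisson intervals of counting error. Open triangles mark libraries with 0 UMIs, drawn at the level of 3 counts. Sdc1 lies at 412 to 580.5 CPM in 3 plasma cell libraries and at 7.41 CPM in the library labelled bone marrow long-lived.

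The first comparison asked how B cells cultured with LPS for 2 hr differ from naive cells. No library was cultured without LPS, so LPS, culture and handling cannot be told apart in these differences. Immediate early and NF-kB response genes were higher at 2 hr than in naive cells, with 36 of 41 measured members at least 2-fold higher and none lower. Among them the orphan nuclear receptors Nr4a3 and Nr4a1 were 142-fold (38.9 to 1175) and 60.6-fold (45.9 to 81.8) higher, the NF-kB regulator Nfkbiz 41.5-fold (31.4 to 55.8) and the chemokine gene Ccl4 129-fold (58.9 to 352), the last with UMIs in 6.20% of cells. Myc (chromosome 15, 61985391 to 61990374, protein-coding) was 37.9-fold higher (31.8 to 45.6), with UMIs in 80.8% of cells against 4.75%. MYC and ribosome biogenesis genes followed the same direction in 36 of 40 measured members, such as Rrp9, Gnl3 and Nolc1 at 7.72-fold (6.51 to 9.21), 7.34-fold (6.48 to 8.34) and 6.45-fold (5.67 to 7.35). Irf4, a transcription factor needed for plasma cell differentiation, was 13.3-fold higher (10.8 to 16.5), while Prdm1 stayed near the floor in both libraries.

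Other genes with large ratios at 2 hr were Il2ra, the interleukin 2 receptor alpha chain, 89.5-fold higher (38.1 to 277), the microRNA 155 host gene Mir155hg (84.9-fold, 58.6 to 128), the survival gene Bcl2l1 (56.1-fold, 33.9 to 101) and the histone demethylase gene Kdm6b (31.9-fold, 24.4 to 42.5). Of 25 measured genes of amino acid transport and tRNA charging, 15 were higher and 2 lower, with the transporters Slc7a5 at 11.1-fold (8.40 to 15.0) and Slc7a1 at 8.54-fold (6.53 to 11.4). The cyclin gene Ccnd2 was 15.9-fold higher (14.5 to 17.5). Glycolysis genes went both ways, with 3 of 18 higher and 4 lower and a median of -0.35 (percentile 9.99), Hk2 at 19.6-fold (12.4 to 32.8) higher and Pdk1 at 4.94-fold (3.19 to 7.90) lower. On the lower side were 17 of 31 B cell identity genes, against 3 higher, including the inhibitory receptors Siglecg (10.4-fold, 9.11 to 11.9) and Cd22 (7.31-fold, 6.28 to 8.54). Interferon response genes were lower in 21 of 25 measured members, with Igtp 17.2-fold (9.08 to 36.6) and Ifi203 8.79-fold (7.38 to 10.5) lower. Homing and egress genes were lower in 19 of 40 and higher in 6, with the sphingosine 1-phosphate receptors S1pr4 and S1pr1 12.6-fold (9.43 to 17.2) and 8.96-fold (7.03 to 11.6) lower. The glycosyltransferase gene B3gnt8 (52.7-fold, 29.2 to 106) and the homeobox gene Hhex (39.0-fold, 26.2 to 60.6) were also among the 10 genes with the lowest ratios.

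By the size rule 1174 of 7122 measured genes were at least 2-fold higher and 1501 lower at 2 hr. This balance turned with TMM scaling (1383 and 1277), median-of-ratios scaling (1403 and 1265) and at least 100 UMIs (1041 and 928). List medians, set against 10000 random lists matched on expression, were 2.66 on the log2 scale for immediate early genes, 1.72 for MYC genes and 1.45 for amino acid genes (each at percentile 100). They were -1.17 for B cell identity, -1.78 for interferon response and -0.84 for adhesion genes (each at percentile 0). The median was -0.77 for survival genes (percentile 0.12), -0.78 for the plasma cell program (percentile 0.32), -0.46 for MHC class II (percentile 1.11) and -0.16 for oxidative phosphorylation (percentile 0.785). Mitosis genes had a median of -1.01 (18 lower and 1 higher of 34, percentile 0.34), which stood at 0.05 without cells over 3 times the median UMI count.

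**Figure D2:**
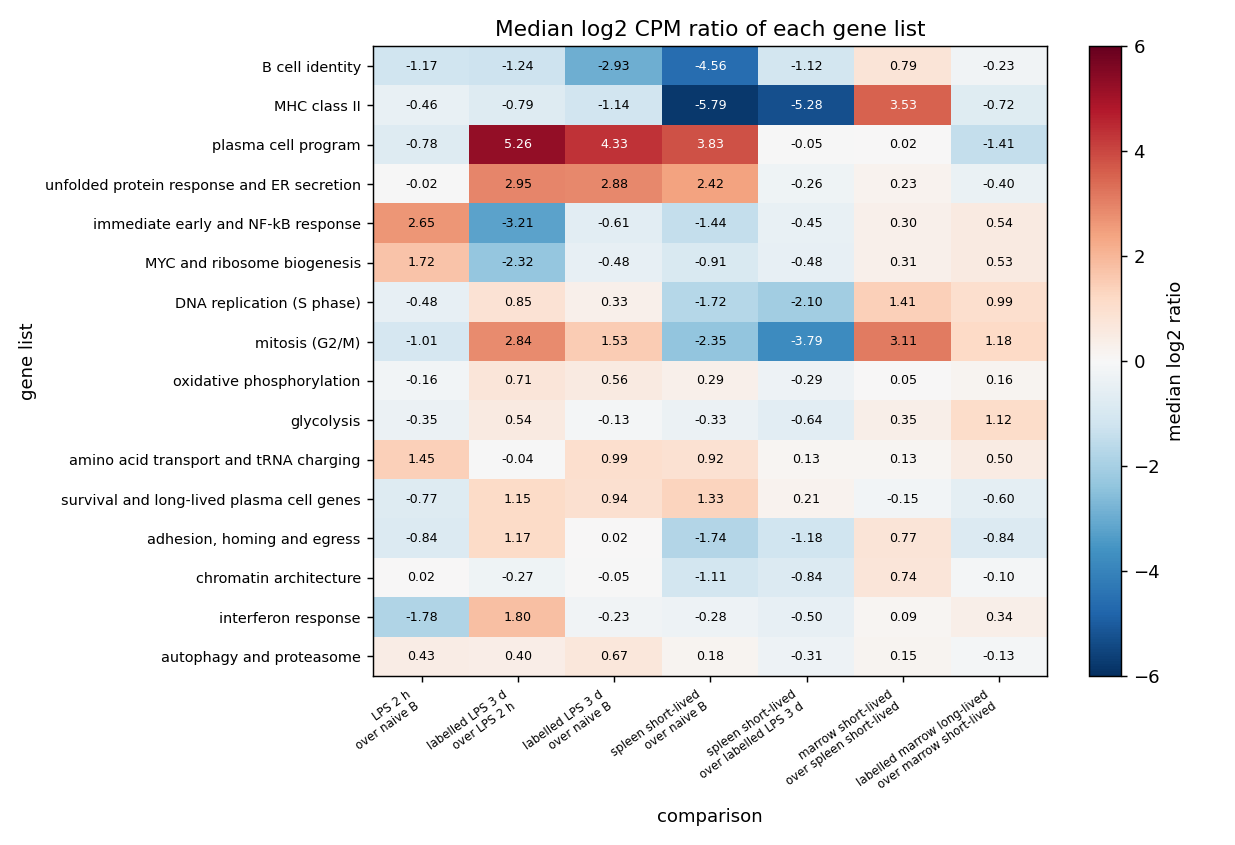
Heat map of the median log2 CPM ratio of each fixed biology list except the gate genes in the 7 comparisons, with the median printed in each cell. At 2 hr against naive cells the immediate early list lies at 2.66 and the interferon list at -1.78.

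The next comparison, of the library labelled 3-day with 2 hr, asked what separates LPS-activated B cells from cultured plasma cells. It rests on a library whose label is among the 3 left open. The plasma cell program was higher in the library labelled 3-day in 22 of 24 measured members, and genes of the unfolded protein response and secretion in 47 of 54. Fkbp11 and Derl3, which act in the endoplasmic reticulum (ER), were 268-fold (156 to 503) and 176-fold (122 to 262) higher, Tnfrsf17, the survival receptor BCMA, 143-fold (48.5 to 693), and the transcription factor gene Bhlha15 174-fold (47.8 to 1439). Xbp1 (chromosome 11, 5520659 to 5525893, protein-coding), the transcription factor of the secretory program, was 35.2-fold higher (31.9 to 39.0), Sdc1 104-fold (70.6 to 162) and Prdm1 31.3-fold (16.8 to 65.7). Slpi, a secreted protease inhibitor, was 144-fold higher (129 to 161), at 7864 CPM. The chemokine receptor gene Ccr10, with 0 UMIs at 2 hr, was at least 105.59-fold higher, and Cxcr3 was 124-fold higher (42.2 to 604).

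Mitosis genes were higher in 37 of 44 measured members and lower in none, such as Ube2c (22.4-fold, 16.9 to 30.2) and Cdk1 (21.2-fold, 14.7 to 31.9). DNA replication genes were higher in 16 of 35 and lower in 3, with Rrm2 15.2-fold (11.9 to 19.6) and Tyms 8.38-fold (6.26 to 11.4) higher. Interferon response genes were higher in 13 of 21, including Isg20 (44.8-fold, 33.2 to 62.1) and Ly6a (22.9-fold, 21.5 to 24.5). This list was lower at 2 hr than in naive cells. In the library labelled 3-day against naive cells 7 of 24 interferon genes were higher and 3 lower, with a median of -0.23 inside the random range (percentile 18.41). Oxidative phosphorylation genes were higher in 20 of 65 and lower in none, with Ndufa1 at 4.33-fold (4.07 to 4.61). The linker histone gene H1f0 was 96.1-fold higher (53.5 to 193), and the chromatin organizer Satb1 131-fold lower (81.5 to 225). Of 42 immediate early genes 34 were lower, in part by construction as both comparisons share the 2 hr library, with Nr4a1 by 934-fold (399.7 to 2877) and the NF-kB subunit gene Rel by 149.6-fold (109.7 to 209.7). Of 41 MYC and ribosome biogenesis genes 36 were lower and none higher, Ddx21 by 12.4-fold (11.1 to 13.8). In the library labelled 3-day against naive cells 28 of 38 genes of this list were within 2-fold, 3 higher and 7 lower. B cell genes were lower in 19 of 31, with Cr2 at 112-fold (62.5 to 226), Bach2 at 34.0-fold (20.98 to 58.8) and Pax5 at 12.4-fold (8.86 to 18.0), and so was Irf4, at 2.11-fold (1.94 to 2.29).

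Of 7221 measured genes 1924 were at least 2-fold higher and 1747 lower. The balance turned with TMM scaling (1821 and 1906), median-of-ratios scaling (1814 and 1922) and the planned filter on markers of other lineages (1611 and 1709). The list medians were 5.26 for the plasma cell program, 2.95 for ER genes and 2.84 for mitosis (each at percentile 100). The median was 1.80 for interferon response (percentile 99.99), 0.85 for DNA replication (percentile 99.89), 0.71 for oxidative phosphorylation (percentile 99.75). On the lower side it was -3.21 for immediate early genes, -2.32 for MYC and -1.24 for B cell identity (each at percentile 0).

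Set against naive cells, the library labelled 3-day had plasma cell genes higher and showed the B cell program lower in 26 of 31 measured members. Derl3 was 75.1-fold higher (57.8 to 99.5), Sdc1 52.6-fold (38.7 to 73.4), Edem1 45.8-fold (39.9 to 52.9), the ER chaperone Hsp90b1 25.4-fold (24.1 to 26.8) and Xbp1 23.0-fold (21.04 to 25.2). ER genes were higher in 49 of 53 and the plasma cell program in 21 of 24. Clec2g (326-fold, 58.2 to 12901) and the cytokine signalling inhibitor Socs2 (263-fold, 46.9 to 10413) had the highest ratios, each against a single UMI in naive cells. Lower genes included Fcer2a (222-fold, 120.3 to 464), Cr2 (154-fold, 85.6 to 309), the lymph node homing receptor Sell (74.2-fold, 51.7 to 110.3), Bcl11a (63.8-fold, 44.2 to 95.6), the B cell transcription factor Ebf1 (36.3-fold, 32.0 to 41.2), Pax5 (32.2-fold, 23.2 to 46.1) and Bach2 (28.1-fold, 17.3 to 48.8). MHC class II genes were lower in 5 of 10, with the class II transactivator Ciita 10.7-fold lower (8.26 to 14.0). Mitosis genes were higher in 32 of 44, with Cks1b at 6.40-fold (5.57 to 7.38). By the size rule 1223 of 7279 measured genes were higher and 1207 lower. The counts were 1125 and 843 with at least 100 UMIs, and turned to 1041 and 1202 with the planned filter on markers of other lineages. List medians were 4.33 for the plasma cell program, 2.88 for ER genes, 1.53 for mitosis and 0.99 for amino acid genes (each at percentile 100), 0.67 for autophagy and proteasome genes (percentile 99.48), and -2.93 for B cell identity (percentile 0).

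The library labelled spleen short-lived was compared with naive B cells to describe plasma cells formed in the animal. Slpi (chromosome 2, 164354070 to 164389095, protein-coding) was 267-fold higher (253 to 282), at 70950.0 CPM. Ly6c2, a cell surface gene, was 159-fold higher (133 to 192), Tnfrsf17 106-fold (51.1 to 263), Sdc1 49.0-fold (36.0 to 68.4), Prdm1 32.4-fold (16.9 to 71.2) and Xbp1 32.6-fold (29.8 to 35.7). The class I-like gene H2-M10.1 was 1770.5-fold higher (489.9 to 14623) and the cytochrome P450 gene Cyp2b10 1770.2-fold (317 to 69944), each against 1 or 2 UMIs in naive cells. Cldn7 and Csn3, with 0 naive UMIs, were at least 291-fold and 284-fold higher. The plasma cell program was higher in 24 of 26 measured members and ER genes in 48 of 53, among them the stress sensor Ern1 (52.8-fold, 17.9 to 258) and Sel1l (21.1-fold, 17.8 to 25.3). Amino acid genes were higher in 12 of 25 and lower in none, with Slc3a2 at 19.7-fold (17.9 to 21.6) and Asns at 17.0-fold (11.8 to 25.3).

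The B cell program was lower in 30 of 31 genes in these cells, with Pax5 (chromosome 4, 44524757 to 44710487, protein-coding) 1172-fold lower (209.8 to 46361, from 1 UMI), Spib 392-fold (152 to 1439.6) and Cd22 360.2-fold (154 to 1111). MHC class II genes were lower in 9 of 10, with H2-Oa 1009-fold (345 to 4898), H2-DMb2 859-fold (479.8 to 1722) and H2-Aa 177-fold (155 to 203) lower. Mitosis genes were lower in 30 of 34 and DNA replication genes in 27 of 31, with Top2a at 13.2-fold (8.87 to 20.5) and Mcm5 at 16.4-fold (10.3 to 27.8). Homing genes were lower in 23 of 40, including S1pr1 (210.1-fold, 81.6 to 774) and Cxcr5 (0 UMIs, at least 291-fold), and the quiescence factor Klf2 was 107-fold lower (83.7 to 139.8). Of the chromatin architecture genes 28 of 51 were lower and 3 higher, with Hmgn2 8.53-fold lower (7.23 to 10.1) and H1f0 29.4-fold higher (20.5 to 43.8). Glycolysis genes were lower in 5 of 18 and higher in 2, with a median of -0.33 inside the random range (percentile 44.26), and Eno1 was 11.7-fold lower (9.91 to 13.9).

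Of 7369 measured genes 1210 were higher and 1973 lower. Of these calls 38.0% were higher, against 52.1% (1571 and 1443) with TMM scaling, which moved the median of all genes from -0.32 to -0.02. List medians were 3.83 for the plasma cell program, 2.42 for ER genes and 1.33 for survival genes (each at percentile 100). They were -4.56 for B cell identity, -5.79 for MHC class II, -2.35 for mitosis, -1.72 for DNA replication, -1.74 for adhesion and -1.11 for chromatin architecture (each at percentile 0). The mitosis median stood at 0.02 under the planned filter on markers of other lineages, which kept 78 spleen cells. The interferon list, at -0.28 (percentile 42.49), stood at 0.02 with TMM scaling, through the same move of all genes.

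Against the library labelled 3-day, the library labelled spleen short-lived differed most in MHC class II and cycling genes. H2-Aa (chromosome 17, 34282744 to 34287823, protein-coding) was at 29.6 CPM in spleen against 3045 CPM, 103-fold lower (89.9 to 118), and H2-Ab1 60.6-fold lower (56.4 to 65.3), with 8 of 9 class II genes lower. Mitosis genes were lower in 43 of 44 measured members and DNA replication genes in 32 of 34, among them Cenpe (38.8-fold, 17.6 to 107), Aurka (35.5-fold, 17.0 to 89.3) and Rrm2 (26.6-fold, 20.1 to 36.0). The T and B cell adhesion gene Cd2 was 52.6-fold lower (34.9 to 83.4), Cxcr3 51.8-fold (27.1 to 114) and the costimulatory gene Cd86 226-fold (40.2 to 8973, from 1 UMI). Homing genes were lower in 23 of 37 with none higher, such as Vim (17.5-fold, 13.9 to 22.5) and Coro1a (11.9-fold, 10.7 to 13.3). Chromatin architecture genes were lower in 22 of 53, with Hmgb2 at 10.6-fold (9.504 to 11.8) and Hmgn2 at 8.50-fold (7.24 to 10.0).

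Higher in spleen were Cyp2b10 (2726-fold, 489 to 107710.0, from 1 UMI), the ceruloplasmin gene Cp (642-fold, 115 to 25381, from 1 UMI), H2-M10.1 (139.8-fold, 102 to 197) and the adhesion gene Epcam (11.8-fold, 10.7 to 13.1). Slpi was 9.02-fold (8.95 to 9.10) and Ly6c2 6.89-fold (6.67 to 7.11) higher, with 9 of 31 survival genes higher and 5 lower. The amino acid genes Slc3a2 (2.93-fold, 2.83 to 3.02), Chac1 (3.01-fold, 2.39 to 3.82) and Asns (2.66-fold, 2.32 to 3.05) were also higher. The plasma cell program lay mostly within 2-fold (19 of 26), with Xbp1 at 3375 against 2379.5 CPM, Irf4 at 153 against 121 CPM and Prdm1 at 59.7 against 53.0 CPM. ER genes were within 2-fold in 43 of 53 and lower in 9, such as Pdia3 (2.73-fold, 2.62 to 2.84) and Hsp90b1 (2.27-fold, 2.24 to 2.31). By the size rule 392 of 6777 measured genes were higher and 918 lower. Of these calls 29.9% were higher, against 47.8% (561 and 613) with TMM scaling, and the median of all genes moved from -0.24 to 0.01. List medians were -5.28 for MHC class II, -3.79 for mitosis, -2.10 for DNA replication, -1.18 for adhesion and -1.12 for B cell identity (each at percentile 0), and 0.21 for survival genes (percentile 99.99).

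By their labels, short-lived plasma cells of the bone marrow and the spleen shared 1 gate, so their comparison asked how the tissues differ, provided that the spleen label is right. Bone marrow cells had higher MHC class II genes, with 7 of 8 measured members at least 2-fold higher, H2-Aa by 43.3-fold (37.6 to 50.04, or 10.3-fold in the 115 of 154 cells lowest in it), H2-Ab1 by 28.2-fold (26.1 to 30.6) and H2-Eb1 by 17.1-fold (15.5 to 19.0). Mitosis genes were higher in 33 of 37 and DNA replication genes in 18 of 27, among them Top2a (24.6-fold, 16.1 to 38.8), Ccna2 (17.7-fold, 10.6 to 30.8), Birc5 (17.0-fold, 11.7 to 25.2) and Rrm2 (9.78-fold, 6.85 to 14.1). B cell identity genes were higher in 9 of 22 and lower in 1, with Cd72 at 20.5-fold (9.64 to 48.7), Siglecg at 12.1-fold (6.77 to 22.4) and Blk at 7.73-fold (4.56 to 13.3), while Ms4a1 was 2.76-fold lower (2.35 to 3.27). Homing genes were higher in 14 of 34 and lower in none, including Cxcr3 (12.7-fold, 5.57 to 31.5), Cd38 (7.59-fold, 5.16 to 11.2) and Cxcr4, the receptor for a bone marrow chemokine (2.53-fold, 1.91 to 3.31). Cd2 was 33.1-fold higher (21.2 to 53.9), and chromatin architecture genes were higher in 20 of 53, with Hmgb2 at 8.14-fold (7.13 to 9.30).

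The genes lower in bone marrow were led by Cyp2b10 (13.3-fold, 9.65 to 19.0), H2-M10.1 (4.98-fold, 4.32 to 5.77), the casein gene Csn3 (4.32-fold, 3.30 to 5.77) and Slpi, at 22604 against 70950.0 CPM (3.14-fold, 3.10 to 3.18). Xbp1 was at 2799 against 3375 CPM, Irf4 at 138 against 153 CPM and Prdm1 at 67.7 against 59.7 CPM, and the 12 measured plasma cell markers all lay within 2-fold. Of 53 ER genes none passed 2-fold. Of 6816 measured genes 709 were higher and 146 lower. The higher calls were 82.9% of both, against 58.7% (426 and 300) with TMM scaling, which moved the median of all genes from 0.22 to -0.09. The planned filter on markers of other lineages, with 17 bone marrow and 78 spleen cells and 716 genes measured, turned the balance to 83 higher and 134 lower. List medians were 3.53 for MHC class II, 3.11 for mitosis, 1.41 for DNA replication, 0.77 for adhesion and 0.74 for chromatin architecture (each at percentile 100). The median was 0.79 for B cell identity (percentile 99.98) and -0.15 for survival genes (percentile 0). That of ER genes, 0.23 (percentile 98.7), stood at -0.09 with TMM scaling, which moves all genes of a library alike and so leaves a list's place among random lists.

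The comparison of B220- with B220+ plasma cells of the bone marrow asked what marks long-lived cells. It rests, however, on a library whose Sdc1 level goes against its label. That library also differed from the other 5 in Xist and the Y-linked genes, so sex cannot be told apart from the other differences here. In the library labelled bone marrow long-lived the plasma cell program was lower in 15 of 26 measured members and higher in none. Sdc1 was 78.3-fold lower (63.8 to 96.9), Ly6c2 98.8-fold (87.7 to 112), the granule protein gene Prg2 66.8-fold (53.4 to 84.4), Tnfrsf17 40.0-fold (26.8 to 61.5) and Epcam 16.8-fold (14.4 to 19.5). Xbp1 was at 1404 against 2799 CPM, Prdm1 at 80.8 against 67.7 CPM and Irf4 at 147 against 138 CPM. Homing genes were lower in 17 of 38, with the integrin Itgb7 at 32.7-fold (19.98 to 55.5) and Ahnak at 83.4-fold (25.3 to 433), and ER genes in 15 of 54, with Ern1 at 5.17-fold (3.72 to 7.12) and Sel1l at 4.51-fold (4.13 to 4.92). Other lower genes were H2-M10.1 (413-fold, 174 to 1285), Xist (257-fold, 190.5 to 356), Cd3g (326-fold, 124 to 1214), Fos (68.3-fold, 42.4 to 115) and, among class II genes, Cd74 (2.71-fold, 2.67 to 2.75) and H2-Ab1 (2.49-fold, 2.41 to 2.58).

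Among higher genes in this library were the transcription factor gene Zbtb32 (77.6-fold, 13.9 to 3069.9, from 1 UMI), the fatty acid receptor Cd36 (60.1-fold, 20.5 to 292, from 3 UMIs), the desaturase gene Scd1 (31.5-fold, 16.0 to 73.0) and the sterol synthesis gene Idi1 (22.3-fold, 10.8 to 55.6). Mitosis genes were higher in 25 of 47 and DNA replication genes in 18 of 37, with none lower, such as Mcm3 (6.72-fold, 3.82 to 13.1), Cdca3 (4.09-fold, 3.18 to 5.37) and Tpx2 (3.82-fold, 2.59 to 5.87). Glycolysis genes were higher in 9 of 16, with Pkm at 3.45-fold (3.12 to 3.83) and Ldha at 3.33-fold (2.91 to 3.82). MYC and ribosome biogenesis genes were higher in 11 of 38, including Npm1 (3.41-fold, 3.14 to 3.71), in a library where ribosomal protein genes took 38.8% of the UMIs against 23.6%. Interferon genes were higher in 9 of 25 and lower in 3, with Ifi27l2a 10.6-fold higher (9.63 to 11.7), Oasl1 at least 30.96-fold higher (0 UMIs in short-lived cells) and Ifi213 13.8-fold lower (10.0 to 19.1). Amino acid genes were higher in 6 of 26 and lower in 2, with a median of 0.50 (percentile 99.97), the serine synthesis gene Psat1 5.48-fold higher (4.12 to 7.45) and Slc3a2 4.31-fold lower (4.06 to 4.58).

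By the size rule 534 of 6925 measured genes were higher and 1361 lower. The higher calls were 28.2% of both, against 47.2% (813 and 911) with TMM scaling and 50.1% (868 and 864) with median-of-ratios scaling. TMM moved the median of all genes from -0.29 to -0.01. List medians were 1.18 for mitosis, 0.99 for DNA replication, 1.12 for glycolysis, 0.53 for MYC and 0.54 for immediate early genes (each at percentile 100). They were -1.41 for the plasma cell program and -0.84 for adhesion (each at percentile 0), -0.40 for ER genes (percentile 0.11) and -0.60 for survival genes (percentile 0.36). With the planned filter on markers of other lineages, which kept 17 short-lived cells, the mitosis, DNA replication, immediate early, plasma cell and ER medians each had the opposite sign. The immediate early median also stood at -0.23 with the mean of per-cell CPM.

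Because depth per cell differed between libraries, the shares of cells with a UMI were taken after each cell was thinned to 800 UMIs, with exact binomial intervals. Mki67, a marker of cycling cells, was found in 0.825% (0.472 to 1.34) of naive cells, 0.361% (0.145 to 0.743) at 2 hr, 8.88% (7.45 to 10.5) of the library labelled 3-day, 0.373% (0.121 to 0.867) of spleen cells, 2.65% (0.726 to 6.64) of bone marrow short-lived cells and 10.1% (8.22 to 12.1) of the library labelled bone marrow long-lived. Top2a, which acts in chromosome separation, was in 1.03%, 0.826%, 5.10%, 0.0745%, 8.61% and 12.9% of the same libraries, with upper bounds of 0.414% in spleen and 14.3% in bone marrow short-lived cells. H2-Aa was in 96.7% of naive cells and 95.9% at 2 hr, in 69.5% of the library labelled 3-day, 1.71% of spleen cells, 39.1% of bone marrow short-lived cells and 51.7% of the library labelled bone marrow long-lived. Thinning left out 60, 63, 48, 30, 3 and 74 cells in that order. Without thinning the Mki67 shares were 2.40%, 1.60%, 26.2%, 2.84%, 24.0% and 55.7%. Fcer2a was found in 22.2% of naive cells at this depth and in 0.210% of the library labelled 3-day. Without thinning it was in 3 of 1372 spleen cells.

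**Figure D3:**
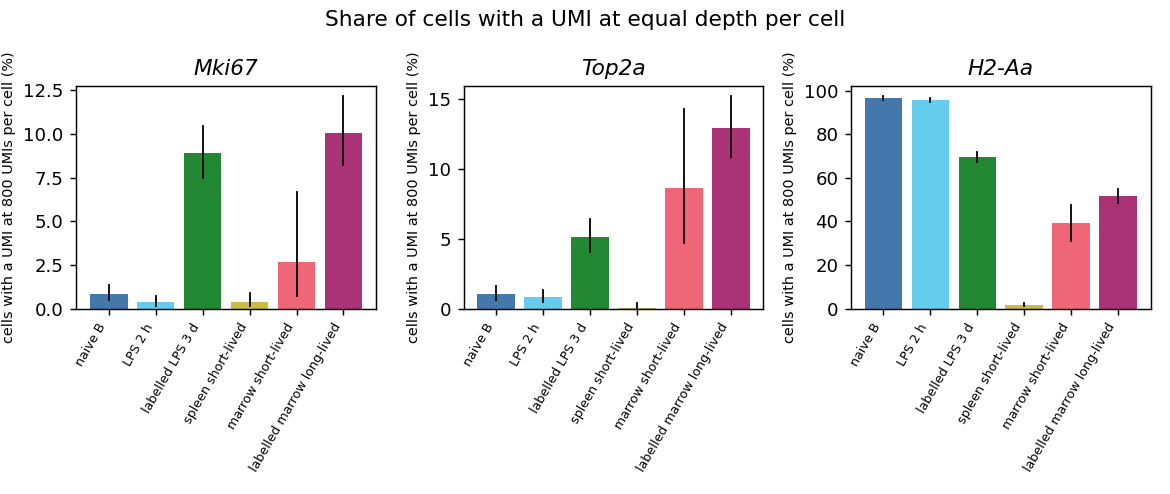
Percent of cells with a UMI of each gene after thinning to 800 UMIs per cell, for 6 libraries, with exact 95% binomial intervals. Mki67 was in 8.88% and 10.1% of the libraries labelled 3-day and bone marrow long-lived, and in 0.373% of spleen short-lived cells.

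Markers of other cell types that the gates could hold were thin in the table, with 21 of 91 markers of 8 non-B lineages present. T cell markers, of which 4 of 14 were present, summed to 56.2 CPM in naive cells, 37.8 at 2 hr, 117 in the library labelled 3-day, 61.9 in spleen, 134 in bone marrow short-lived cells and 11.1 in the library labelled bone marrow long-lived. Cd3g made up most of the T cell sum in 2 of these, at 69.8 CPM in the library labelled 3-day and 92.0 CPM in bone marrow short-lived cells. Monocyte, macrophage and dendritic cell markers summed to 344, 152, 1009, 2073, 1535 and 384 CPM in the same order. Cst3 alone was at 917.8 CPM in the library labelled 3-day, between 1998 and 2063 CPM by its interval in spleen, 1486 CPM in bone marrow short-lived cells and 253.7 CPM in the library labelled bone marrow long-lived. Erythroid markers summed to 85.7 CPM in naive cells and 6.52 to 48.6 CPM elsewhere, stromal or endothelial markers to 85.1 and 10.2 to 38.5 CPM, NK cell markers to 7.36 to 38.6 CPM and neutrophil markers to 0 to 24.2 CPM. The basophil marker found summed to at most 13.5 CPM, and no megakaryocyte marker was in the table.

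Of the B lineage marker lists, follicular genes were lower in 5 of 11 at 2 hr, in 9 of 11 in the library labelled 3-day and in 10 of 11 in spleen plasma cells against naive cells, with medians of -0.45, -3.72 and -7.47. Plasma cell markers were higher in 12 of 12 in the libraries labelled 3-day and spleen against naive cells, with medians of 4.69 and 5.02. In the library labelled bone marrow long-lived against bone marrow short-lived, 7 of 12 were lower and none higher, with a median of -1.49 (percentile 0). Germinal centre markers were lower in 4 of 5 in spleen plasma cells against naive cells, with a median of -5.35, and marginal zone or B1 markers were higher in 4 of 7, with a median of 1.15 that stood at -1.08 with no gene minimum. Of pro-B or pre-B markers 3 of 11 and of stem cell markers 1 of 8 were in the table. The gate list itself had 6 of 12 genes in the table, with 3 of 6 higher and 3 of 6 lower in spleen plasma cells against naive cells.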

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

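No paired analysis was possible because there was 1 library per group and no replicate numbers. A list median is called reversed where it lay outside the central 95% of random lists and changed sign, and otherwise the same inside its 95% order-statistic interval and moved outside it. A gene's log2 ratio is called reversed where it was at least 2-fold and changed sign, and otherwise the same inside its counting interval and moved outside it. By this rule, of 1480 list medians under the alternatives 1368 were the same, 97 moved and 15 reversed, and 100 changed sign in all. Of 5803 log2 ratios of named genes 4881 were the same, 911 moved and 11 reversed, and 30 changed sign in all. The cause was not tested for any of these except where a sentence gives it. Low depth limits the bone marrow short-lived library most, with 154 cells. Scaling by all UMIs changed nothing, as no immunoglobulin chain gene is in the table. Heavy and light chain shares, with their threshold alternative, were not run for the same reason.

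Each scaling multiplies all genes of a library by 1 factor, so a sign change under it is a shift of all genes alike and leaves a list's place among random lists. This holds for 3 of the 15 reversed list medians, the ER medians below. With TMM scaling, bone marrow against spleen short-lived gave 426 higher and 300.0 lower genes and an unfolded protein response and ER secretion median of -0.0856. The library labelled bone marrow long-lived against bone marrow short-lived gave 813 higher. With median-of-ratios scaling the first comparison gave 439 higher and 279 lower and an ER median of -0.0581, and the second 868 higher and 864 lower. Median-of-ratios scaling over 4 libraries, chosen after seeing the data, gave 437 higher, 281 lower and -0.0599 in the first comparison.

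With no gene minimum, which lets in more genes by construction, lower genes at 2 hr against naive were 2375. Higher and lower genes were 687 and 1431 for spleen against the library labelled 3-day, 1352 and 364 for bone marrow against spleen short-lived, and 827 and 2097 for the library labelled long-lived against short-lived. The gate gene median of the library labelled 3-day against naive reversed to 0.0471 and the marginal zone or B1 median of spleen against naive to -1.08. With at least 100 UMIs, which leaves fewer genes, the counts were 928 lower at 2 hr against naive, 228 higher in bone marrow against spleen short-lived and 797 lower in the library labelled long-lived against short-lived.

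The planned filter on markers of another lineage kept 231, 78, 17 and 138 cells of the library labelled 3-day, spleen, bone marrow short-lived and library labelled long-lived. With Cst3 not counted it would keep 1119, 1207, 104 and 549. Spleen against naive then had 1250.0 lower genes, with a mitosis median of 0.0234 and a Top2a log2 ratio of 0.0234, the middle gene of that list, from 2 spleen UMIs. The median of all measured genes was 0 there. With 112459 spleen UMIs left, genes with 0 spleen UMIs could be set to a log2 ratio of 0 by the floor rule. How much of the fall from 1973 lower genes this made was not tested. Spleen against the library labelled 3-day had 125 higher and 603 lower, and bone marrow against spleen short-lived 83 higher and 134 lower and an ER median of -0.52. Ciita in the library labelled 3-day against 2 hr was at 0.19. The library labelled long-lived against short-lived had 593 lower genes, and medians of 0.0851 for the plasma cell program, 0.54 for ER genes, -0.99 for immediate early, -1.10 for DNA replication, -1.68 for mitosis and 1.11 for plasma cell markers. Its log2 ratios were -0.83 for Cotl1, -0.15 for Cdca3, -1.39 for Tpx2, -0.28 for Cenpa, -0.31 for Ran, -1.02 for Ezh2, 1.03 for Map1lc3a, 0.33 for Ndufa1 and 1.03 for Slc3a2. These ratios rest on few of the 41891 bone marrow short-lived UMIs left. The counts were 1 for Map1lc3a, 4 for Cotl1, 5 for Cdca3, Tpx2 and Slc3a2, and 6 for Cenpa. They were 9 for Ezh2, 19 for Ran and 20 for Ndufa1. Under a filter that both leaves out Cst3 and requires 2 different markers, chosen after seeing the data, no list median reversed and every gene count stayed within 1.5 times its main value.

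With the mean of per-cell CPM, lower genes in bone marrow against spleen short-lived were 230.0, and the immediate early median of the library labelled long-lived against short-lived was -0.23. Without cells over 3 times the median UMI count the mitosis median at 2 hr against naive was 0.0469. Thinned to 500 UMIs, Mki67 was in 5.24% (4.16 to 6.504) of the library labelled 3-day and 8.38% (6.73 to 10.3) of the library labelled long-lived, and Top2a in 3.13% of the first, 4.61% of bone marrow short-lived cells and 6.87% of the library labelled long-lived. In the same single draw Mki67 was in 4.61% of bone marrow short-lived cells and Top2a in 0.220% of spleen cells, above their values at 800 UMIs and within those intervals. Without thinning, which keeps the depth differences, Mki67 was in 2.40%, 1.60%, 26.2%, 2.84%, 24.0% and 55.7% of naive, 2 hr, 3-day-labelled, spleen, bone marrow short-lived and long-lived-labelled cells. Top2a was in 3.00%, 2.60%, 16.9%, 0.948%, 16.2% and 51.7% of the same libraries.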

Other observations

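The genes and tests of this part were chosen after the results were seen, and so were the bounds of the tests. Idi1, a sterol synthesis gene, was at 115 CPM in the library labelled bone marrow long-lived and 5.15 to 14.9 CPM in the other 3 plasma cell libraries, and Sqle was at 78.5 against 8.39 to 9.56 CPM. Hmgcs1 was at 49.4 against 2.94 to 6.66 CPM, Scd1 at 185 against 5.89 to 11.1 CPM and the fatty acid receptor gene Cd36 at 133 against 1.76 to 2.80 CPM. At 2 hr of LPS Idi1 was at 139.6 CPM against 20.7 CPM in naive cells, and Hmgcs1 at 121 against 23.6 CPM. The cell cycle inhibitor gene Cdkn2a was at 238.5 CPM in the library labelled bone marrow long-lived, 32.6 CPM in the library labelled 3-day, 25.8 CPM in bone marrow short-lived and 10.7 CPM in spleen cells.

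The library labelled bone marrow long-lived had little Sdc1, with Mki67 in 10.1% (8.22 to 12.1) and Top2a in 12.9% (10.8 to 15.2) of cells after thinning, against 8.88% (7.45 to 10.5) and 5.10% (4.02 to 6.37) in the library labelled 3-day. An exchange of its label with the 3-day label alone would put the long-lived cells in the library labelled 3-day, where the 8.88% with Mki67 lay above the upper bound of 0.867% in spleen. That argues against it, on the textbook point that long-lived plasma cells do not divide. By the same point, Mki67 in 10.1% of cells goes against the long-lived label as given. The rotation described below would put the long-lived cells in the library labelled spleen, with Mki67 in 0.373%. The library labelled bone marrow long-lived had little Xist and carried Y-linked transcripts, as male cells do, while the other libraries carried Xist, as female cells do. Sex can act on genes of any chromosome, so its effect cannot be told apart from the other differences of that library. A rotation of the 3-day, spleen and long-lived labels, with spleen short-lived cells in the library labelled 3-day, was left undecided by its test. Of 154 bone marrow short-lived cells 83 (53.9%, 45.7 to 61.95) were nearest to the library labelled 3-day and 56 (36.4%, 28.8 to 44.5) to spleen. The first interval spans the bound of 50%. Both shares come from the same 154 cells of 1 library, so their intervals cannot be set against each other. Bone marrow short-lived also correlated more with the library labelled 3-day than with spleen (Pearson 0.971 and 0.961 of log2 CPM). The library labelled 3-day had 197 genes higher and 372 lower than bone marrow short-lived, which had 709 higher and 146 lower than spleen. With TMM scaling the counts lay closer, at 234 and 343 for the first pair and 426 and 300 for the second. These values go with the rotation, but rest on 1 library per group. In the other direction 1330 of 1372 cells labelled spleen and 1166 of 1479 cells of the library labelled 3-day were nearest to bone marrow short-lived. Each cell's own library was left out, so the shares come from different sets of libraries. Long-lived bone marrow cells under the spleen label could also be nearest to bone marrow short-lived, so these shares decide nothing. Of 1029 cells labelled bone marrow long-lived, 558 (54.2%) were nearest to the library labelled 3-day, 253 (24.6%) to naive and 183 (17.8%) to bone marrow short-lived. That library correlated with 2 hr at 0.822, against 0.776, 0.761 and 0.716 for the 3-day-labelled, bone marrow short-lived and spleen libraries. Its correlation with naive was 0.863, against 0.852, 0.832 and 0.780. These values too rest on 1 library per group and do not decide the labels. A biological difference of B220- cells was not tested.

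MHC class II genes were higher in bone marrow than in spleen short-lived cells. Naive follicular B cells mixed in at the share the H2-Aa level needs would bring Fcer2a to 72.2 CPM, and 0 UMIs were seen, which allows up to 2.71 CPM. Few cells carried most of the H2-Aa, since leaving out all but the 115 lowest of 154 removed 81.7% of its UMIs, but the ratio was still 10.3 (8.68 to 12.3) there and 5.34 (4.24 to 6.70) in the 77 lowest, which argues against a minority as the whole cause. Cycling cells are argued against by a class II median of 3.32 among 65 and 1248 cells without UMIs of 12 cycling genes. RNA released by cells high in class II was not tested and could hold up those lower ratios, and a difference between the tissues stays open only if the spleen label is right.

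Cd3g, the CD3 gamma chain gene of T cells, was found in 189 of 1479 cells of the library labelled 3-day and 31 of 154 bone marrow short-lived cells. In the first, T cells or doublets with them are argued against by 2.26 CPM of Lck and Lat in cells with Cd3g, where 398.8 CPM would be needed. A median UMI ratio to other cells of 0.824 argues only against doublets of high UMI count. In bone marrow short-lived cells Lck and Lat were at 13.6 CPM, where 285.9 CPM would be needed. The bound for this test was changed after its outcome was seen, from 10% of the needed level, which left the bone marrow result undecided with an upper bound of 34.8 CPM, to the lower counting bound of the needed level, 183.2 CPM, so that result depends on the bound. The needed level comes from 16 naive-library cells with Cd3g and 4 of 14 T cell markers are in the table, so what Cd3g marks in these cells stays open.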
